A study of Arabidopsis thaliana with 16 samples.

How the data were processed

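RNA of 12 samples was hybridised to Affymetrix ATH1 arrays, with 4 replicates each of methanol, TA and IXB, and each replicate combined 2 flasks of 100 mL. The labels call the replicates biological and do not say whether they came from separate parent cultures, so the p-values measure the spread between these samples, part of which may be technical. The names thaxtomin A and isoxaben for TA and IXB are general knowledge about the compounds and not from the labels. The deposited values are on a log2 scale and were made by the authors with RMA, per the submitters' processing notes, which give no version or settings. RMA corrects background, brings the arrays to a common distribution and summarises the probes of a probe set, so an overall shift of all transcripts in a group is not visible, and small changes of dim transcripts are compressed.

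The 4 methanol arrays appear once in the TA set and once in the IXB set, and per the labels the control scans are the same in both. The 2 versions of an array correlated at r = 0.9969 to 0.9972 when matched by replicate number and at 0.992 to 0.995 otherwise. Their deviations from the set mean correlated at 0.807 to 0.873 when matched and at -0.510 to 0.015 otherwise, so a number marks 1 array in both sets. Column medians averaged 4.79 log2 in the TA set and 5.25 in the IXB set. Tests against methanol were therefore made within a set of 8 columns, and levels are not compared across sets. For TA against IXB every column was expressed as its deviation from the methanol mean of its own set, and the 2 versions of a methanol array were averaged and counted once, which left 12 arrays. This step removes an offset between the sets but not a difference in the scale of their log2 changes, which was not tested.

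Of 22810 probe sets, 64 Affymetrix controls were left out and 22746 were tested. The annotation table used here lists 14016 of these, of which 13513 belong to exactly 1 gene and 503 to several, and leaves 8730 unnamed here. Of the single-gene probe sets, 13436 matched a locus of the TAIR10.1 gene table, which served for names only, and they stand for 13355 genes, 11798 of which carry their locus tag as a symbol. No coordinates are given, since no genome build is named for the array. CESA1, CESA3 and CESA6, catalytic subunits of the primary wall cellulose synthase, are not analysed here because no listed probe set of exactly 1 gene stands for them.

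Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted with the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and with an estimated correlation as an alternative. A gene entered by its brightest single-gene probe set, and p-values were adjusted over the 7 lists that had at least 5 measured genes. A count "adjusted over the list alone" uses the p-values of the list's members only. Of 27 lists written, the list of cytosolic ribosomal proteins was left out because the tables give no descriptions, and the callose synthase and jasmonate lists had 0 measured genes. Exact permutation tests were made in R, and figures in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.

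The groups, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took, for each compound, the 12 largest increases and the 12 largest decreases among single-gene probe sets that passed the threshold with all 4 treated arrays beyond all 4 methanol arrays. It added up to 4 members of each list with the largest change past the threshold, or the 1 with the largest change if none passed, and CESA1, CESA3 and CESA6. For TA against IXB it took the 10 largest differences in each direction and up to 2 members of each list. Gene families formed from symbols with at least 8 members, the low-oxygen list and its use as a covariate were chosen after seeing the data.

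Same-numbered arrays were checked for pairing by the correlation of their deviations from the group means. For methanol and IXB these were 0.147, 0.102, 0.133 and 0.144, all above 0.1, which treats the numbers as pairs, although no label says that a number marks a shared culture or day and only 2 of 4 arrays correlated best with their own number. With the pairs as a block the IXB counts were 625 higher and 189 lower.

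The alternatives were a replicate block, an intensity trend or a robust prior in eBayes, an ordinary linear model, array weights, other thresholds, the removal of dim probe sets (mean log2 value under 5) and of probe sets that can bind related transcripts, 1 probe set per gene, quantile normalization again, median centring, other sets of arrays in the fit, and leaving out each array in turn. Because both compounds share the methanol arrays, the overlap and correlation of their changes were set beside 100 simulations of unchanged groups and beside fits with the methanol arrays split.

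The code was tested on simulated data for 22746 probe sets, of which 67 were changed by 0.5 log2, 67 by 1 and 66 by 2. For TA against methanol 59.7%, 97.0% and 100% of these were recovered in turn, with 4 false calls among 175. For IXB against methanol the shares were 62.7%, 95.5% and 100%, with 11 false calls among 183, and for TA against IXB 70.2%, 98.5% and 100%, with 8 among 187. A shifted gene list was called in all 3 simulations, and 1 unshifted list was called as well in the one for TA and 0 in the others. Before the shift, 1 of 7 lists was called in the simulation for TA and 0 in the others. The noise was drawn for each probe set on its own, so the genes of a list did not move together. These simulations therefore do not measure how often lists of correlated genes are called with no shift.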

Results

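Transcript levels were measured in suspension-cultured cells of Arabidopsis thaliana, ecotype Landsberg erecta, kept in the dark, after contact with either of 2 inhibitors of cellulose synthesis. Thaxtomin A (TA, a phytotoxin made by Streptomyces that cause potato scab) was given at 2 µM and isoxaben (IXB, a synthetic herbicide) at 100 nM, each in methanol, and control cultures received 20 µL of methanol alone. Cells were treated on day 3 after sub-culture and frozen after 6 h. Each of the 3 groups had 4 replicates, each a pool of 2 flasks, and each replicate was hybridised to 1 Affymetrix ATH1 array, which gave 12 arrays. The 4 methanol arrays appear in both the TA set and the IXB set, so the values fill 16 columns. Median log2 values of the columns ran from 4.76 to 4.85 in the TA set and from 5.204 to 5.302 in the IXB set, and between 47.8% and 52.6% of probe sets had a log2 value of at least 5. Each compound was therefore compared with methanol within its own set. The number of arrays limits the precision of every value, and the median standard error of a log2 fold change was 0.090 for TA and 0.086 for IXB.

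The first comparison asked which transcripts changed after 6 h with TA. XTH18, a xyloglucan endotransglucosylase/hydrolase, rose 11.3-fold, from a log2 value of 6.57 ± 0.14 with methanol to 10.06 ± 0.11 with TA (SD, n = 4). AT2G47550, a pectin methylesterase, rose 10.1-fold, from 6.36 ± 0.26 to 9.69 ± 0.05 (SD, n = 4), and ATPMEPCRB, another pectin methylesterase, rose 5.91-fold. AT1G33760, an ERF/AP2 transcription factor, rose 8.10-fold, AT2G34930, a leucine-rich repeat protein, 7.18-fold, AT4G27280, an EF-hand calcium-binding protein, 6.75-fold, and AT5G39580, a peroxidase, 6.48-fold. CML38, a calmodulin-like protein, rose 6.24-fold, CCR2, a cinnamoyl-CoA reductase, 6.16-fold, AT2G32190 10.7-fold, AT1G20070 6.87-fold and AT5G38700 5.64-fold. With the mean of a low-oxygen gene list, described below, as a covariate the log2 fold change of CML38 was 1.49 and its call was lost (adjusted p = 0.621), while the other genes named here kept theirs.

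Decreases with TA were smaller. The largest among named genes was that of AT5G12970, which fell by 0.94 log2 (SE 0.08, limma adjusted p = 6.92e-06), from 6.30 ± 0.08 to 5.37 ± 0.12 (SD, n = 4). AT3G10080 (log2 change -0.85), AT4G03100 (-0.82), AT3G28420 (-0.80), AT5G45700 (-0.80), AT5G55520 (-0.79), AT5G07810 (-0.77), AT5G01910 (-0.74), AT1G66830 (-0.73), AT3G61820 (-0.72), AT4G03790 (-0.70) and AT5G66230 (-0.69) also fell. The probe set of AT4G03790 is of a type that can also bind related transcripts, so its value is uncertain. All 12 decreases lost the call with the low-oxygen covariate (adjusted p of at least 0.0791). AT5G55520 was then at -0.23, AT3G61820 at -0.31, AT4G03790 at -0.35 and AT5G45700 at -0.49. The others ran from -0.62 (AT5G07810) to -1.02 (AT5G12970), with AT3G28420 at -0.97, AT4G03100 at -0.86 and AT5G66230 at -0.69. Standard errors rose, from 0.08 to 0.22 for AT5G12970, so a lost call does not by itself mark a smaller change.

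Over the 22746 probe sets tested with limma, 1230 were higher and 1069 lower with TA at an adjusted p under 0.05, which is 10.1% of them. Called increases had a median of 0.58 log2 and called decreases a median of -0.40. The largest increase was 3.62 log2, on a probe set that is unnamed here, and the largest decrease -0.96. At least 1 log2 separated TA from methanol for 253 probe sets that were higher and 0 that were lower, and 0 decreases of that size had an unadjusted p under 0.05 either. In 1168 of the higher and 991 of the lower probe sets, all 4 TA arrays lay beyond all 4 methanol arrays. Of all probe sets, 16.02% were separated in that way, where chance gives 2.86%. The count of lower probe sets was 637 without methanol replicate 2 and 659 without TA replicate 3. The counts were 765 higher and 477 lower with an ordinary linear model, and 127 higher and 1 lower with the low-oxygen mean as a covariate.

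Of 15 genes known to respond to low oxygen, 12 rose with TA, 1 rose with IXB, and the others did not pass. This list was written after other such genes, left out of it, had been seen among the largest differences between the compounds on these arrays, so its values are not independent evidence of its direction. Limma's camera, adjusted over 29 families, gave adjusted p = 5.72e-16 for TA, 0.0152 for IXB and 3.99e-09 for TA against IXB, and all 3 calls were lost with an estimated correlation (adjusted p = 0.331, 0.920 and 0.371). The IXB call was also lost without methanol replicate 2 (adjusted p = 0.175) or IXB replicate 3 or 4 (adjusted p = 0.229 and 0.231), and without dim probe sets (adjusted p = 0.152), while without IXB replicate 1 its adjusted p was 9.19e-10. The mean difference between IXB and methanol was 0.62 log2 without IXB replicate 1, 0.19 and 0.21 without IXB replicates 3 and 4, and 0.21 without methanol replicate 2. Its mean lay at 1.08 ± 0.23 log2 above the methanol mean with TA, 0.34 ± 0.60 above it with IXB and 0 ± 0.28 with methanol (SD, n = 4). The 4 TA arrays stood at 1.29, 0.79, 1.23 and 1.01, the 4 IXB arrays at -0.51, 0.34, 0.78 and 0.75, and the 4 methanol arrays at 0.01, -0.39, 0.09 and 0.29. An exact two-sided permutation test gave p = 0.0286 for TA against methanol, the smallest that 4 against 4 arrays allow, and p = 0.371 for IXB against methanol (Benjamini-Hochberg adjusted over the 3 comparisons of the groups, 0.0429 and 0.371). Among the genes that rose with TA were AT5G66985 (log2 fold change 2.102) and AT5G10040 (2.05).

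**Figure D1:**
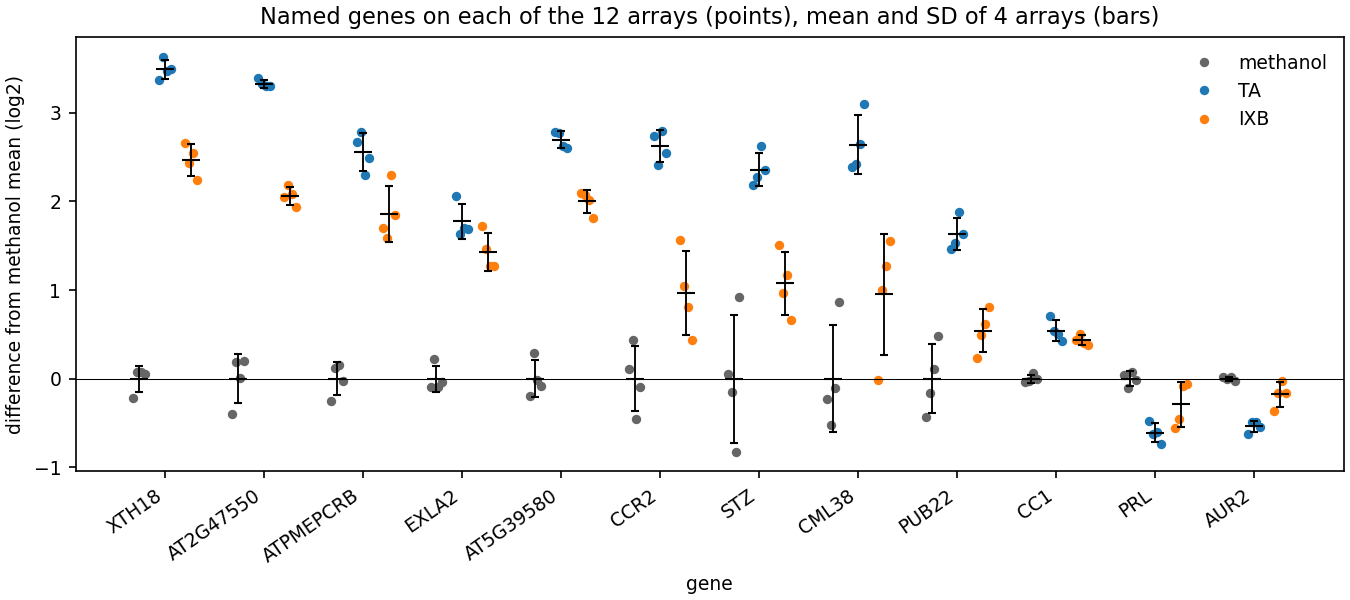
Log2 difference of each of the 12 arrays from the methanol mean (vertical axis) for 12 named genes (horizontal axis), with points for arrays and bars for the mean and SD of 4 arrays per group. XTH18 lies near 3.49 with TA and 2.47 with IXB, while STZ and CML38 vary widely among the methanol arrays.

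Several gene lists shifted with TA, each represented by only part of the genes written for it. Of 8 measured genes of the early elicitor response, 6 rose and 2 did not pass the test, and 7 were higher when adjusted over the list alone. STZ, a zinc-finger transcription factor, rose by 2.36 log2, the ubiquitin ligases PUB22 and PUB23 by 1.63 and 1.37, and WRKY6 by 0.52. Of 9 xyloglucan endotransglucosylase/hydrolases, 4 rose and 5 did not pass (5 higher when adjusted over the list alone), with XTH19 at 1.72, XTH16 at 0.67 and XTH33 at 0.38 after XTH18. XTH16 and XTH33 were dim, at 2.67 and 3.12 log2 with methanol, and so were XTH21, XTH26 and XTH32, which did not pass. Without dim probe sets too few of these enzymes remained to test the list. Of 10 calcium and touch response genes, all of them calmodulin-like, 4 rose and 6 did not pass (4 when adjusted over the list alone), with CML46 at 1.51, CML23 at 0.75 and CML37 at 0.54. Of 5 genes of primary wall cellulose synthesis, CC1, a companion of cellulose synthase, rose by 0.54 and COB, a glycosylphosphatidylinositol-anchored protein, by 0.43. The other 3, CC2, STL1 and STL2, did not pass (3 of the 5 higher when adjusted over the list alone). No catalytic subunit (CESA) was among the 5. The low-oxygen genes moved with each of these lists, since they too were higher on all 4 TA arrays. With their mean as a covariate XTH18, XTH19 and CML46 kept the call. The other genes named here lost it (adjusted p of at least 0.0788). The changes of STZ (1.59), PUB23 (1.18), PUB22 (0.98), CML37 (0.42) and CC1 (0.36) were then smaller. Those of XTH16 (0.83), WRKY6 (0.69), COB (0.52) and XTH33 (0.49) were larger, and that of CML23 (0.76) was about the same. Their standard errors rose, from 0.10 to 0.26 for XTH16. Limma's camera gave adjusted p = 1.07e-08 for the elicitor list, 1.71e-06 for the xyloglucan enzymes, 7.51e-06 for the calcium list and 4.87e-04 for primary wall synthesis, and all 4 calls held with an estimated correlation between genes (adjusted p = 0.00543, 0.00664, 0.00664 and 0.0237).

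The 3 remaining lists gave weaker results with TA. Of 14 expansins, 3 rose, 1 fell and 10 did not pass, and the counts were also 3 and 1 when adjusted over the list alone. The 3 that rose are expansin-like A genes, EXLA3 by 2.04, EXLA2 by 1.77 and EXLA1 by 1.40, and EXPB3 fell by 0.55. Of 6 auxin response genes, WES1, an auxin-conjugating enzyme, fell by 0.50 and IAA29, a repressor of auxin signalling, by 0.44, while 4 did not pass (2 lower when adjusted over the list alone). Of 7 WRKY transcription factors, WRKY6 rose by 0.52 and WRKY53 by 0.49, and 5 did not pass (2 when adjusted over the list alone). Camera gave adjusted p = 0.0224 for the expansins, 0.0412 for the auxin list, towards lower values, and 0.0491 for the WRKY list. With an estimated correlation all 3 calls were lost (adjusted p = 0.110, 0.131 and 0.110). The expansin call was also lost without TA replicate 3 (adjusted p = 0.0548), and the auxin call without methanol replicate 1 (adjusted p = 0.114) or TA replicate 4 (adjusted p = 0.106). The WRKY call was lost without methanol replicate 1, 2 or 4 or TA replicate 2, 3 or 4 (adjusted p between 0.0532 and 0.0908). The 3 expansin-like A genes kept the call with the low-oxygen covariate, and EXPB3, WES1, IAA29, WRKY6 and WRKY53 lost it (adjusted p of at least 0.529). EXPB3 was then at -0.20 and WES1 at -0.36. IAA29 (-0.43) was about as large as before and WRKY6 (0.69) and WRKY53 (0.67) were larger, with larger standard errors.

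**Figure D2:**
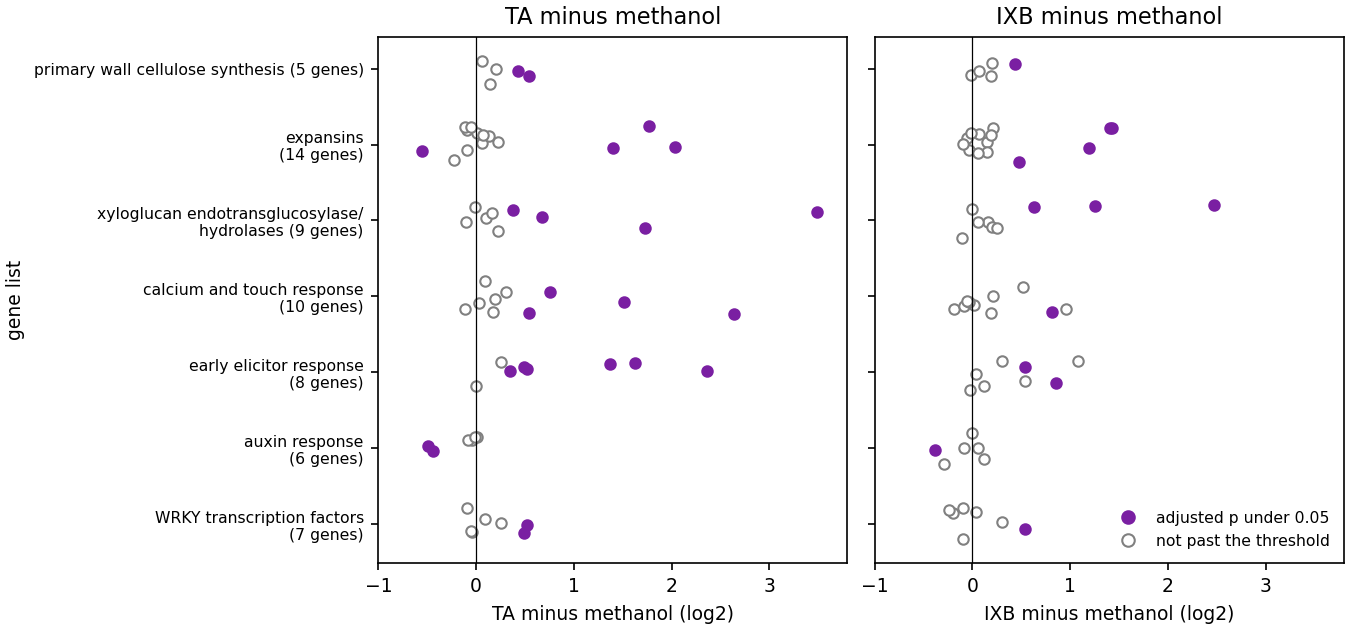
Log2 fold change (horizontal axes) of each measured gene of 7 lists (vertical axis) with TA (left) and IXB (right) against methanol, with filled points for an adjusted p under 0.05. Among the elicitor genes 6 of 8 points are filled with TA and 2 of 8 with IXB.

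Lists with under 5 measured genes were described without a test of the list. They held few of the genes written, such as 1 of 21 for ethylene and 4 of 25 for cell death. With TA, the pectin genes ATPMEPCRB and PME34 rose (2.56 and 1.62 log2) of 4 measured, and 3 were higher when adjusted over the list alone. The phenylpropanoid genes CCR2 and HCT rose (2.62 and 0.86) of 3. SAG101, of the salicylic acid list, rose by 0.93 and COR47, a dehydrin of the abscisic acid list, by 0.82, each 1 of 2. HSP17.6C, a small heat shock protein, rose by 0.57, 1 of 3. PRL, a subunit of the MCM helicase and the 1 S phase gene measured, fell by 0.61. Of 3 mitosis genes AUR2, an Aurora kinase, fell by 0.54 and TOPII, a topoisomerase, by 0.44, while AUR1 (-0.16) did not pass. These counts were the same when adjusted over the list alone except for pectin. None of the measured genes passed in the wall-sensing (3 genes), xenobiotic (4), secondary wall (2), extensin (2), sugar metabolism (1), ethylene (1), tryptophan (1), cell death (4), photosynthetic (1) and root hair (2) lists. Of these 21 genes, 4 were higher and 0 lower at an unadjusted p of limma under 0.05. Adjusted over the list alone, 2 wall-sensing and 2 xenobiotic genes were higher. The member farthest from methanol was MIK2 (0.36), UGT73B4 (0.83), GUT2 (0.12), LRX4 (0.06), USP (-0.06), PDF1.2 (0.04), IGPS (-0.01), ALPHA-VPE (-0.12), RCA (0.01) and EXPA7 (-0.10) in these lists in turn. The call of HSP17.6C was lost without methanol replicate 1, 2, 3 or 4 or TA replicate 3 or 4 (adjusted p between 0.0528 and 0.113), and UGT73B4 was at 0.53 without methanol replicate 3. Only ATPMEPCRB, PME34 and CCR2 kept the call with the low-oxygen covariate (adjusted p of at least 0.130 for the others). TOPII was then at -0.19, HSP17.6C at 0.31 and SAG101 at 1.41. HCT (0.95), COR47 (0.86), PRL (-0.77) and AUR2 (-0.50) were about as large as before or larger, with larger standard errors.

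The second comparison asked the same of IXB. XTH18 was again the named gene with the largest increase, at 5.54-fold, from 6.88 ± 0.15 with methanol to 9.35 ± 0.18 with IXB (SD, n = 4). AT1G33760 rose 4.67-fold, AT4G27280 4.65-fold, AT2G47550 4.19-fold, AT5G39580 4.00-fold and ATPMEPCRB 3.63-fold. AT2G32190 rose 3.18-fold, GH9B5, a family 9 glycosyl hydrolase, 3.06-fold, and AT4G02170 3.03-fold. EXLA2 rose 2.70-fold, TET9, a tetraspanin, 2.66-fold and EXLA3 2.65-fold.

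AT2G04850 fell most with IXB, by 0.69 log2 (SE 0.07, limma adjusted p = 1.59e-04), and AT5G12970 fell by 0.66. SIM, an inhibitor of cyclin-dependent kinases, fell by 0.57, FANCM, a DNA helicase, by 0.53 and RCK, a meiotic helicase, by 0.50. AT2G16365 (-0.56), AT5G37900 (-0.54), AT4G03100 (-0.54), AT1G50910 (-0.51), AT3G47270 (-0.50), AT3G03170 (-0.50) and AT4G15830 (-0.49) also fell. AT3G47270 is measured by a probe set that can bind related transcripts, so its value is uncertain. Leaving out 1 array ended the call of AT2G16365 (IXB replicate 3, adjusted p = 0.05001), of FANCM (methanol replicate 1 or 2 or IXB replicate 3, up to 0.0625), of SIM (methanol replicate 1, 2 or 4 or IXB replicate 2 or 4, up to 0.0616), of AT4G03100 (any but methanol replicate 2 and IXB replicate 3, up to 0.0764) and of AT3G03170 (any but methanol replicate 1 and IXB replicate 3, up to 0.116). AT3G03170 also lost it with the low-oxygen covariate (adjusted p = 0.0707), where it was at -0.47.

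In all, 501 probe sets were higher and 184 lower with IXB, 3.01% of the 22746 tested. Their median changes were 0.54 and -0.37 log2, and the largest 2.62, on a probe set unnamed here, and -0.69. An increase of at least 1 log2 was seen for 80 called probe sets and a decrease of that size for 0, and for 0 at an unadjusted p under 0.05. All 4 IXB arrays lay beyond all 4 methanol arrays in 497 of the higher and 183 of the lower probe sets. Among all probe sets that share was 11.6%, where chance gives 2.86%. The count of lower probe sets fell whichever array was left out. It was 54, 69, 152 and 58 without methanol replicates 1, 2, 3 and 4, and 63, 58, 105 and 89 without IXB replicates 1, 2, 3 and 4. All IXB calls kept their sign in these fits, which have fewer arrays and so less power to pass the threshold. The count of higher probe sets was 319 without methanol replicate 1 and also 319 without IXB replicate 2. An ordinary linear model gave 164 higher and 48 lower, and with the low-oxygen mean as a covariate 287 were lower.

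Expansins and xyloglucan enzymes shifted with IXB. Of 14 expansins, 4 rose and 10 did not pass (4 when adjusted over the list alone): EXLA2 by 1.43, EXLA3 by 1.41, EXLA1 by 1.19 and EXPA15 by 0.47. Of 9 xyloglucan endotransglucosylase/hydrolases, XTH18, XTH19 (1.251) and XTH16 (0.63) rose and 6 did not pass (4 higher when adjusted over the list alone). XTH16 was dim in this set as well, at 2.98 log2 with methanol. Of 8 elicitor genes, PUB23 rose by 0.85 and WRKY53 by 0.54, and 6 did not pass (4 higher when adjusted over the list alone). CC1 rose by 0.43, the 1 of 5 primary wall synthesis genes that passed (1 when adjusted over the list alone). CML46 rose by 0.82 and the other 9 calcium and touch genes did not pass (4 higher when adjusted over the list alone). IAA29 fell by 0.38 and 5 auxin genes did not pass (1 lower when adjusted over the list alone). Of 7 WRKY genes, WRKY53 rose and 6 did not pass (1 higher and 1 lower when adjusted over the list alone). The mean of the low-oxygen genes on the IXB arrays ranged from -0.51 to 0.78.

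Camera gave adjusted p = 9.89e-07 for both the expansins and the xyloglucan enzymes and 2.19e-05 for the elicitor list with IXB, and these 3 calls held with an estimated correlation (adjusted p = 0.0251, 0.0148 and 0.0148). Primary wall synthesis (adjusted p = 0.00632) and the calcium list (adjusted p = 0.0375) lost their calls with an estimated correlation (adjusted p = 0.115 and 0.105). The auxin list (adjusted p = 0.249) and the WRKY list (adjusted p = 0.865) were not called, and the WRKY list had a negative median (-0.10) and a direction towards lower values but a positive mean (0.03). The calcium call was also lost after quantile normalization again (adjusted p = 0.0521), and without methanol replicate 1 or 2 or IXB replicate 2 or 4 (adjusted p = 0.101, 0.0505, 0.0586 and 0.0619). EXPA15 lost its call without methanol replicate 4 or IXB replicate 1, 2 or 4 (adjusted p up to 0.0732).

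Among the small lists, ATPMEPCRB (1.86 log2) and PME34 (1.17) rose with IXB of 4 pectin genes, and 3 were higher when adjusted over the list alone. CCR2 (0.96) and HCT (0.62) rose of 3 phenylpropanoid genes, HSP17.6C (1.17) of 3 heat shock genes, and THE1, a receptor kinase that senses the wall (0.53), of 3 wall-sensing genes. Adjusted over the list alone, the counts were 2, 1 and 3. None passed in the salicylic acid, abscisic acid, S phase, mitosis, ethylene, xenobiotic, secondary wall, extensin, sugar metabolism, tryptophan, cell death, photosynthetic and root hair lists. At an unadjusted p of limma under 0.05, 2 of these 26 genes were higher and 4 lower. When adjusted over the list alone SAG101 (0.55), COR47 (0.35), PRL (-0.29) and PDF1.2 (-0.36) passed. In the other lists the member farthest from methanol was TOPII (-0.23), UGT73B4 (0.65), IRX15 (0.10), LRX5 (-0.11), USP (0.03), IGPS (0.02), DELTA-VPE (-0.16), RCA (-0.13) and EXPA7 (0.15). UGT73B4 was at 0.36 without methanol replicate 3, at 0.32 without IXB replicate 1 and at 1.08 with the low-oxygen covariate, where it passed (adjusted p = 0.0257), and TOPII was at -0.15 without IXB replicate 3. With that covariate SAG101 (0.66), COR47 (0.42) and PRL (-0.42) passed as well (adjusted p = 0.0332, 0.0122 and 0.0188). Leaving out 1 array ended the call of HCT (methanol replicate 4 or IXB replicate 1 or 3, adjusted p up to 0.0670), of THE1 (methanol replicate 1 or 4 or IXB replicate 1, 2 or 4, up to 0.0866) and of CCR2 (any but methanol replicate 2 and IXB replicate 4, up to 0.0931).

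The third comparison set TA against IXB directly, at doses that differ, over deviations from the methanol mean of each set. AT2G34930 was 3.96-fold higher with TA than with IXB, AT1G20070 3.798-fold, AT2G32190 3.35-fold, CML38 3.22-fold and CCR2 3.16-fold. AT2G17850 (log2 difference 1.48), AT4G33560 (1.2999), AT5G38700 (1.29), STZ (1.28) and AT2G47550 (1.26) followed. AT2G29500, a small heat shock protein, lay lower with TA than with IXB by -0.95 log2 (SE 0.17, limma adjusted p = 0.00550), with fold changes against methanol of 1.32 for TA and 2.55 for IXB. AT1G35280 (-0.81), AT5G15950 (-0.76), AT2G07360 (-0.76), the chloroplast gene ycf4 (-0.67), AT5G07810 (-0.67), AT2G07170 (-0.60), AT5G02180 (-0.60), AT3G50690 (-0.60) and AT3G59670 (-0.59) were lower with TA as well. A further probe set of AT2G07360 gave -0.38, and the probe set of AT1G35280 can bind related transcripts.

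Some of these differences lost the call when 1 array was left out, which also leaves fewer arrays to test with. AT1G35280, AT2G17850, AT4G33560 and AT5G02180 each lost the call without any of 6 or 7 arrays (adjusted p up to 0.111, 0.116, 0.101 and 0.0943), among them TA replicates 1 and 3 and IXB replicates 1 and 2 for all 4 genes. Without IXB replicate 1 the difference was 0.97 log2 for AT2G17850 and 0.83 for AT4G33560, and with the low-oxygen mean as a covariate it was 0.16 and 0.17. Both are known to respond to low oxygen. That covariate also ended the calls of AT2G29500, AT1G35280, AT2G07170, AT3G59670, AT5G02180 and ycf4 (adjusted p between 0.1145 and 0.288). Their differences changed far less, to -0.76, -0.67, -0.58, -0.53, -0.53 and -0.68 in turn, and their standard errors rose. AT3G59670 lost the call without TA replicate 1 or 3 or IXB replicate 2 or 4 (adjusted p up to 0.0688), AT2G07170 without TA replicate 1 or 3 or IXB replicate 4 (up to 0.0634), and ycf4 without IXB replicate 2 or 4 (up to 0.0554). Without TA replicate 4 the difference of ycf4 was -0.44. The other arrays that ended a call were methanol replicate 4, TA replicate 2 and IXB replicate 4 for AT1G35280, methanol replicate 1 and TA replicate 4 for AT2G17850, methanol replicate 1 and TA replicates 2 and 4 for AT4G33560, and TA replicate 2 and IXB replicates 3 and 4 for AT5G02180.

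Between the compounds, 618 probe sets were higher and 467 lower with TA than with IXB, 4.77% of the 22746 tested, with median differences of 0.44 and -0.37 log2. Differences of at least 1 log2 numbered 41 towards TA and 0 towards IXB, and 0 towards IXB at an unadjusted p under 0.05. The count of higher probe sets was 397 without TA replicate 3, 336 without IXB replicate 2 and 329 without IXB replicate 4. The count of lower probe sets was 295, 275 and 218 without TA replicates 1, 2 and 3, and 224, 150 and 159 without IXB replicates 1, 2 and 4. It was 257 when the 8 treated arrays alone gave the spread. The counts were 358 and 260 with an ordinary linear model and 255 and 75 with the low-oxygen mean as a covariate. They were 1839 and 1947 without the step that centres each set on its methanol mean, with the treated columns quantile normalized together instead.

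Calcium and elicitor genes were higher with TA than with IXB. Of 10 calcium and touch genes 3 were higher and 7 did not pass (5 higher when adjusted over the list alone), with CML38 at 1.69 and CML46 at 0.69. Of 8 elicitor genes 4 were higher and 4 did not pass (4 when adjusted over the list alone), with STZ at 1.28 and PUB22 at 1.09. Given the low-oxygen covariate, CML38, CML46 and STZ lost the call (adjusted p = 0.111, 0.0815 and 0.0591) and PUB22 (0.77) kept it. CML38 was then at 0.87, while CML46 (0.63) and STZ (1.38) stayed about as large with larger standard errors. CML38 followed the low-oxygen mean in part. Among the IXB arrays it was lowest on replicate 1 (-0.0187 log2 from methanol), as that mean was (-0.5076). Among the TA arrays it was highest on replicate 4, where that mean was not highest. The difference of CML38 can therefore not be read as separate from the low-oxygen pattern. Both lists had camera adjusted p = 3.02e-04, and both calls held with an estimated correlation (adjusted p = 0.00936 for each). Whether the calcium call depends on CML38 was not tested. The mean of the low-oxygen genes was also higher with TA than with IXB, by 0.74 log2 (exact permutation p = 0.0286, the smallest possible, adjusted 0.0429), and without IXB replicate 1 the difference was 0.46 (exact permutation p = 0.0571). Because that list was written after such genes were seen among the largest differences between the compounds, these p-values are not independent evidence. Of its 15 genes 4 were higher with TA than with IXB and 11 did not pass.

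XTH18 (1.02) and XTH19 (0.47) were higher with TA than with IXB, 2 of 9 xyloglucan enzymes (2 when adjusted over the list alone), with adjusted p = 0.0348 for the list. Of 7 WRKY genes 0 passed limma's test (0 when adjusted over the list alone, and 3 higher at an unadjusted p under 0.05), with adjusted p = 0.0460 for the list. Both calls were lost with an estimated correlation (adjusted p = 0.0850 for each). Primary wall synthesis (0 of 5, and 1 higher when adjusted over the list alone or at an unadjusted p under 0.05, adjusted p = 0.0975), expansins (EXLA3 at 0.63, 1 of 14; 2 higher and 2 lower when adjusted over the list alone; adjusted p = 0.408) and auxin genes (0 of 6, when adjusted over the list alone and at an unadjusted p under 0.05 too, adjusted p = 0.303) were not called as lists. The xyloglucan call was lost without TA replicate 2 or 3 or IXB replicate 2 or 4 (adjusted p between 0.0534 and 0.0867), and XTH19 without TA replicate 2 or 4 or IXB replicate 1, 2 or 4 (up to 0.0928). XTH19 also lost its call with the low-oxygen covariate (adjusted p = 0.121), where its difference was 0.53 and its standard error larger. The WRKY call was lost with median centring (adjusted p = 0.0517), and without methanol replicate 1 or 4, TA replicate 2, 3 or 4 or IXB replicate 2, 3 or 4 (between 0.0572 and 0.103).

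Among the small lists, ATPMEPCRB (0.70) and PME34 (0.45) were higher with TA than with IXB, and so were CCR2 (1.66), COR47 (0.47) and PDF1.2, a defensin (0.39), while AUR2 was lower (-0.36). The numbers past the test when adjusted over the list alone were 2, 1, 1, 1 and 1 in the pectin, phenylpropanoid, abscisic acid, ethylene and mitosis lists, and HSP17.6C (-0.59) and PRL (-0.32) were lower by that measure. No gene of the other small lists passed over all probe sets or over its list alone, and over the 26 genes of all small lists with no call 1 was higher and 3 lower at an unadjusted p of limma under 0.05. PME34 lost its call without TA replicate 1 or 3 or IXB replicate 2 or 4 (adjusted p up to 0.0877), and PDF1.2 without methanol replicate 3, TA replicate 1, 2 or 4 or IXB replicate 1 or 2 (up to 0.103). ATPMEPCRB and PDF1.2 lost theirs with the low-oxygen covariate (adjusted p = 0.135 and 0.245), where they were at 0.60 and 0.34 with larger standard errors.

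The changes with TA and IXB were also set side by side. Of the 501 probe sets higher with IXB, 417 (83.2%) were higher with TA as well, and of the 184 lower with IXB, 85 (46.2%) were lower with TA, while 0 were called in opposite directions. Independent lists of these sizes would share 27.1 higher and 8.65 lower probe sets. In 100 simulations of unchanged groups against the shared methanol arrays 0 were shared, but unchanged groups give too few calls for this count to measure what the shared arrays add. Over the probe sets higher in both, the median increase was 0.94 log2 with TA and 0.61 with IXB, and 188 of them were higher with TA than with IXB and 1 lower. Of the 813 called higher with TA and not with IXB, 271 differed between the compounds in that direction, and of the 84 called higher with IXB and not with TA, 31 were higher with IXB.

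Across all probe sets, which are not independent replicates, the log2 fold changes of TA and IXB correlated with Pearson's r = 0.747 and Spearman's rho = 0.546. Unchanged groups against the same methanol arrays gave a mean r of 0.5003 and a highest of 0.523. The covariance was 0.0371, against 0.00549 in those simulations. Genes that move together on real arrays can make both values vary more between unchanged groups than in those draws, so 0.523 is not a limit for chance. With the methanol arrays split into 2 for TA and the other 2 for IXB, in all 6 ways, 162 to 235 probe sets were higher in both and 3 to 8 lower in both, r was 0.510 to 0.623 and the covariance 0.0298 to 0.0342. The shared lower count was 24, 30 and 30 without methanol replicates 1, 2 and 4, and 30, 36, 41 and 47 without IXB replicates 1, 2, 3 and 4.

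**Figure D3:**
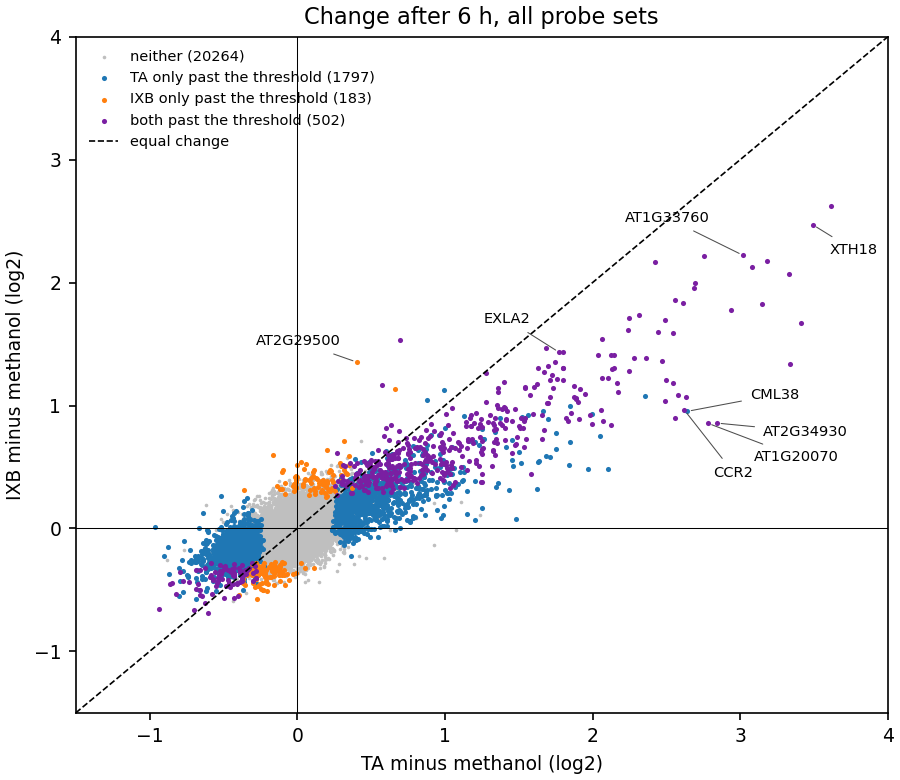
Log2 fold change with TA (horizontal axis) against that with IXB (vertical axis) for all 22746 probe sets, coloured by which comparison passed an adjusted p under 0.05, with a dashed line for equal change. Among the 417 probe sets higher in both, most of the largest changes lie below the line, as XTH18 does at 3.49 and 2.47.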

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

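The comparison of single arrays and the tests of list differences were set before the result was seen, and the 3' minus 5' signal of control probe sets and the choice of which pattern to follow came after.

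In 26 of 310 groups of 4 arrays (8.39%, where chance gives about 5%) 1 array stood apart from the other 3, measured as its gap to the nearest array over the range of the group. Values are deviations from the methanol mean in log2 and the gap follows. Among methanol arrays, replicate 1 was apart for XTH18 (-0.22 against 0.06 to 0.08, gap 0.926), XTH19 (gap 0.840), IRX15 (0.833), PUB23 (-0.22 against 0.07 to 0.08, gap 0.983), AT2G07170 (0.853) and AT3G50690 (0.852). Replicate 2 was apart for TOPII (0.887), replicate 3 for AT5G02180 (0.881) and for the mean of the WRKY list (0.05 against -0.02 to -0.01, gap 0.948), and replicate 4 for AT5G37900 (0.916).

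Among TA arrays, replicate 1 was apart for AT3G10080 (-0.52 against -0.998 to -0.930, gap 0.858), EXLA2 (2.06 against 1.64 to 1.71, gap 0.842) and CML37 (gap 0.854), replicate 2 for AT4G33560 (gap 0.876), and replicate 3 for AT5G55520 (-1.26 against -0.68 to -0.61, gap 0.888) and GUT2 (gap 0.854). Replicate 4 was apart for AT5G66230 (gap 0.831), TOPII (-0.17 against -0.54 to -0.52, gap 0.928) and ycf4 (-1.05 against -0.20 to -0.08, gap 0.877). Among IXB arrays, replicate 1 was apart for EXLA3 (gap 0.853), replicate 3 for AT4G03790 (0.897), CML46 (1.29 against 0.63 to 0.70, gap 0.885) and CML23 (0.887), and replicate 4 for AT2G04850 (-0.56 against -0.73 in the others, gap 0.944) and EXPA7 (0.891).

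The 3' probe set of the actin control exceeded its 5' probe set by 4.32 log2 on TA replicate 4 and by 3.76 to 3.78 on the other TA arrays (gap 0.970), while the methanol arrays of that set had 3.92 to 4.24. Without TA replicate 4, 1144 probe sets were higher and 1137 lower with TA than with methanol, and 538 were higher and 460 lower with TA than with IXB. For the GAPDH control the 3' minus 5' value was -0.17 to 0.0008 on the IXB arrays, below the 0.01 to 0.22 of the methanol arrays of that set. For the actin and ubiquitin controls the IXB and methanol arrays overlapped.

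Between TA and IXB, 4 gene lists differed in the test of the difference itself: calcium and touch response (adjusted p = 0.000302 with limma's camera), early elicitor response (adjusted p = 0.000302), xyloglucan endotransglucosylase/hydrolases (adjusted p = 0.0348) and WRKY transcription factors (adjusted p = 0.0460), all towards higher values with TA. The xyloglucan call was lost without TA replicate 2 or 3 or IXB replicate 2 or 4 (adjusted p between 0.0534 and 0.0867), and the WRKY call without methanol replicate 1 or 4, TA replicate 2, 3 or 4 or IXB replicate 2, 3 or 4 (adjusted p between 0.0572 and 0.103). Both were also lost with an estimated correlation (adjusted p = 0.0850 for each). Whether the calcium call depends on CML38, whose difference went from 1.69 to 0.87 with the low-oxygen covariate, was not tested.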

How the results depend on the processing

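The low-oxygen covariate and the gene families were chosen after the result was seen, and the other alternatives before. All called probe sets that were tested again kept their sign in every refit but 2: with the covariate 96.0% of the TA calls did, and without methanol centring 98.6% of the TA against IXB calls. Of the named genes past the threshold, 0 of 51 with TA, 0 of 38 with IXB and 0 of 30 between them lost the call under the replicate block, the intensity trend, quantile normalization again or median centring. Over all arrays left out in turn, 6 such calls were lost and 402 kept with TA, 39 and 265 with IXB, and 51 and 309 between them, and the covariate ended 34, 1 and 14. Arrays give no read depth: dim probe sets near background limit what small changes can be seen.

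Counts are given as higher and lower, for TA, IXB and TA against IXB in turn. At 1 log2 or more they were 253 and 0, 80 and 0, and 41 and 0, and at an adjusted p under 0.01 they were 810 and 397, 226 and 16, and 220 and 67. With 1 probe set per gene, where fewer were tested, they were 652 and 503, 234 and 79, and 343 and 256. An ordinary linear model gave 765 and 477, 164 and 48, and 358 and 260, with no variance shared between probe sets. With the low-oxygen covariate they were 127 and 1 for TA, 287 lower for IXB, and 255 and 75 between them. Lower counts with IXB were 307 without dim probe sets and 279 with array weights. Between the compounds, the 8 treated arrays alone gave 257 lower, and no methanol centring gave 1839 and 1947. With the covariate the median standard error of the TA calls rose from 0.092 to 0.238 and that of the calls between the compounds from 0.088 to 0.113. For its count with IXB, array weights, the treated arrays alone and no centring the cause was not tested.

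With 1 array left out, so with fewer samples, the counts ranged from 637 to 1137 (TA lower), 319 to 487 (IXB higher), 54 to 152 (IXB lower), 329 to 677 and 150 to 535 (TA against IXB, higher and lower). Without dim probe sets only 3 lists, the xyloglucan enzymes not among them, kept enough genes to be tested, and the number called was 3 for TA, 3 for IXB and 1 between them. With an estimated correlation it was 4, 3 and 2, and leaving out 1 array gave 2 to 4 between the compounds. The count lower with both compounds was 157 without dim probe sets and 24 to 85 with 1 array left out, and the correlation 0.804 and 0.694 to 0.756. With 2 methanol arrays for TA and the other 2 for IXB, higher in both, lower in both and r were 205, 4 and 0.510 (replicates 1 and 2 with TA), 179, 3 and 0.618 (1 and 3), 162, 3 and 0.623 (1 and 4), 224, 8 and 0.574 (2 and 3), 217, 3 and 0.621 (2 and 4), and 235, 8 and 0.570 (3 and 4).

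With the replicate block the counts were 1316 and 1181 for TA and 687 and 566 between the compounds. Same-numbered methanol and TA arrays correlated at -0.06 to 0.295 and TA and IXB arrays at -0.02 to 0.107, and 2 of 4 and 1 of 4 correlated best with their own number. The block took the WRKY list with TA to an adjusted p of 0.0503 and the TET family with IXB to 0.0541, and ended no other call among the lists, families and named genes.

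Among the named genes and gene lists, direction turned only for results not past the threshold, apart from the low-oxygen list with IXB, whose own mean was then the covariate, and for the others the cause was not tested. With the covariate LRX4 (-0.10), USP (0.042), IGPS (0.024) and RCA (-0.039) with TA turned, as did the WRKY list (adjusted p = 0.751) and the low-oxygen list itself (adjusted p = 0.778) with IXB and the expansins between the compounds (adjusted p = 0.624). RCA with TA also turned under quantile normalization again (-0.021) and median centring (-1.4625e-05), and ran from -0.015 to 0.032 over left-out arrays. Left-out arrays gave PDF1.2 -0.026 to 0.125, IGPS -0.017 to 0.0034 and EXPA7 -0.159 to 0.0042 with TA, and USP -0.013 to 0.080 and IGPS -0.0059 to 0.042 with IXB. The WRKY list with IXB turned under the replicate block (adjusted p = 0.975) and over left-out arrays (adjusted p between 0.665 and 0.982), and the expansins between the compounds without dim probe sets (adjusted p = 0.621).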

Other observations

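The gene families, the low-oxygen list, the 2 tests of its array means, its use as a covariate and the ratios from it, the test of centring and the counts of lists over other splits were chosen after the result was seen, and the other tests before.

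Several gene families formed from symbols were called, but none of these calls held with an estimated correlation between genes, and members are named here after their values were seen. Of 9 plant U-box ubiquitin ligases (PUB), 3 of which are also elicitor genes, 4 rose with TA (adjusted p = 2.18e-04 with limma's camera over 29 families, and 0.331 with an estimated correlation), 1 with IXB (adjusted p = 0.00501 and 0.247), and 4 were higher with TA than with IXB (adjusted p = 0.0125 and 0.269), with PUB43 at 0.61, 0.16 and 0.44 log2. Of 15 tetraspanins, 3 rose with TA (adjusted p = 0.0139 and 0.331), TET9 by 2.15, TET8 by 2.06 and TET3 by 0.47, and 2 with IXB (adjusted p = 0.0226 and 0.439). The IXB call of this family was lost with the replicate block, and without methanol replicate 2 (adjusted p = 0.175) or IXB replicate 3 (adjusted p = 0.110). Of 11 RALF-like signalling peptides (RALFL), 3 rose with IXB (adjusted p = 0.00501 and 0.439) and 3 with TA, where the family did not pass (adjusted p = 0.0932), with RALFL28 at 1.26 and 1.28, and the family was not called between the compounds (adjusted p = 0.853).

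Further families were called, again with no call that held with an estimated correlation. Of 10 VPS genes of vesicle sorting, 4 were higher with TA than with IXB (adjusted p = 0.00946 with limma's camera, and 0.371 with an estimated correlation), with VPS60.1 at 0.50, and 3 rose with TA (adjusted p = 0.0299 and 0.331), a call lost without methanol replicate 3 (adjusted p = 0.0568) or TA replicate 4 (adjusted p = 0.0725). Of 8 autophagy (ATG) genes ATG8H was higher with TA than with IXB, by 0.79 (family adjusted p = 0.00850 and 0.416), and it rose with TA by 1.03 (family adjusted p = 0.0449 and 0.463), a call lost without methanol replicate 3 or TA replicate 2 or 4 (adjusted p = 0.110, 0.116 and 0.133). Of 11 PRA genes 3 rose with TA (adjusted p = 0.0251 and 0.331), PRA1.B4 by 1.18, and 2 were higher with TA than with IXB (adjusted p = 0.0283 and 0.371), a call lost without TA replicate 1 or 3 or IXB replicate 1 or 2 (adjusted p up to 0.0845). Of 12 ubiquitin-specific proteases (UBP), 2 fell with TA, UBP26 by 0.42 and UBP21 by 0.40 (adjusted p = 0.0449 and 0.331, towards lower values). That call was lost with quantile normalization again (adjusted p = 0.0584) and without methanol replicate 2, 3 or 4 or TA replicate 2 or 4 (adjusted p between 0.0517 and 0.0943). The 47 UDP-glycosyltransferases (UGT) had a mean of 0.14 with IXB (adjusted p = 3.01e-05 and 0.194), where limma called 0 of them over all probe sets and 10 were higher at an unadjusted p under 0.05. They were shifted towards lower values with TA than with IXB (adjusted p = 0.00307 and 0.269), with 3 lower, among them UGT71B1 at -0.52.

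Of 15 genes known to respond to low oxygen, 12 rose with TA against methanol and 4 were higher with TA than with IXB, and the calls of the list were lost with an estimated correlation (adjusted p = 0.331 and 0.371). Exact permutation of their array means gave p = 0.02857 for both contrasts (0.0571 without IXB replicate 1 for the contrast with IXB), but because the list was chosen on these arrays and its genes move together, this does not argue against variation between flasks, which stays open, as do handling that followed the group and an effect of TA itself. As the whole source of the other changes, a low-oxygen state was predicted to take them below 0.5 of their size with its mean as a covariate. The median ratio was 0.898 (quartiles 0.562 and 1.18) for TA and 0.960 (0.809 and 1.104) for TA against IXB, so most changes kept over 0.5 of their size. That does not decide the question. The list means of the TA arrays all lay above those of the other groups, so the slope came from the spread within groups. The calls had also been chosen on these arrays. The ratio was under 0.5 for 492 of 2287 TA calls and 40 of 1081 calls between the compounds. Among them were AT2G17850 (1.48 to 0.16 between the compounds), AT4G33560 (to 0.17 from 1.2999) and AT5G55520 (-0.79 to -0.23 with TA), while CML38 went from 1.69 to 0.87 between the compounds. With the covariate 128 probe sets were called for TA, 127 of them called without it too, and the median standard error rose from 0.092 to 0.238.

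Decreases were smaller than increases with both compounds. A signal floor of dim probe sets would make them equal among bright ones, but among 3037 probe sets with a methanol mean of at least 8 the value exceeded by 0.1% of them was 1.87 with TA, and 0.1% lay below -0.68, a ratio of 2.74, which argues against it as the whole source. Centring of the arrays stays open: the median of all fold changes was -0.0142, but RMA itself holds that median near 0, so the value decides nothing. That transcripts can fall within 6 h only as fast as they decay is a candidate explanation that was not tested.

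Other splits of the 8 arrays of each comparison into 4 and 4, 35 with the real one, were run to see how often chance gives as much. For changed probe sets the real split ranked 1 of 35 for TA, with 2299 called and the highest other 0. It did so between the compounds too, with 1085 and the highest other 173. By the smallest unadjusted p of a gene list with limma's camera it also ranked 1 of 35, with 1.53e-09 against 6.19e-06 for TA and 6.66e-05 against 1.26e-04 between the compounds. By the number of lists called it ranked 1 for TA (7, highest other 4), but between the compounds another split called more (4, highest other 5). A rank of 1 in 35 is the smallest share possible, and the shares were not adjusted over these outcomes. Every other split puts arrays of the same treatment on both sides, which widens the spread and lowers its calls. The gaps in counts therefore do not measure how unlikely chance is. For IXB, whose numbers were taken as pairs with methanol, the real split was set against those that also part all pairs, since the others leave some pairs on 1 side. These are 8 with the real one, too few for a share under 0.05. They gave 685 called probe sets and the highest other 0, a smallest list p with limma's camera of 2.59e-07 against 1.71e-04, and 5 lists against 4.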
